A study of Homo sapiens with 16 samples.

How the data were processed

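RNA from U2OS cells was measured by RNA sequencing in 16 libraries, 2 replicates for each combination of a number (zdna1 to zdna4) and an arm (CC or CL). Per the labels, RNA was extracted with Trizol and libraries were made with an Abclonal kit. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.6 and aligned with STAR, bedtools 2.29.2 was used, and the genomes named are hg19 and dm6, with no role given for each. Per the file headers, fragments over exons were counted per gene with featureCounts 2.0.1 in paired mode with no strand option, against hg19 plus the contig of the library's own number, so antisense reads and reads over overlapping genes cannot be assigned to a strand.

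The deposited values are not whole numbers but a scaled signal: in each library nearly all values are whole multiples of its smallest step (0.115 to 0.802 per read), and a folder name in the headers holds the word spikein, which fits counts multiplied by 1 constant per library. The constant is not stated, so how it was obtained is unknown. Dividing by the step recovered whole reads within 0.1 read for at least 99.99% of the nonzero values of every library; paired reads count as 1 read here. The scale of the deposited values was kept as an alternative, called the deposited scale.

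The files give 28207 human gene symbols with hg19 positions, and positions printed are those of the files. Depth was 39335 to 310187 human-gene reads per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Reads of near-identical gene copies, such as RN7SL1 and RN7SL2, the spliceosomal and 5S RNAs, histones and actins, cannot be fully told apart by unique alignment.

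Changes were tested with limma 3.58.1 on log2 of CPM plus 10, with TMM factors from edgeR 4.0.16 over the 4632 human genes with a mean of at least 50 CPM. A single fit held the 8 group means and all 16 libraries, with array weights estimated per group, a mean-variance trend fitted on human genes alone, and Benjamini-Hochberg adjustment at 0.05 within each comparison; tests were two-sided. The plan assumed whole counts and named edgeR's quasi-likelihood test, which was run on the recovered reads as an alternative together with DESeq2 1.42.0. The comparisons were CL over CC in each number and averaged over the numbers, the test that these 4 differences are equal, the test of any difference among numbers averaged over the arms, and the 6 pairs of numbers. Pairs that share a number share its libraries. The contig was tested beside the human genes in the comparisons of arms, with the prior spread of the most abundant human gene, and left out of the comparisons of numbers, because each number has its own. Counts of genes never include it.

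The labels do not say whether replicates are separate cultures, so the spread between replicates, and each p-value, may reflect technical spread alone. Chi-square tests of read counts did not separate the replicates beyond counting noise in zdna2 CC (p = 0.383), zdna3 CC (p = 0.674) and zdna3 CL (p = 0.0705), but the contig's share differed in each of the 8 pairs (p at most 0.00181), and the deposited values of replicates were equal only for 15 genes of zdna4 CC, so each was kept as 2 libraries. Replicate numbers gave no sign of pairing libraries: deviation correlations over 28 pairs of libraries ran from -0.0195 to 0.0431, and a model with a replicate block is given among the alternatives.

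Gene lists (32, written from textbook knowledge) were tested with camera on log2 CPM with prior count 2 and a preset correlation of 0.01 between genes, for the 27 lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists in each of 11 comparisons. Of 297 tests camera called 75, of which 51 held with an estimated correlation. Rotation tests with fry, which ask whether a list's genes move one way on balance without comparing them with other genes, called 108. Counts of members are given over all genes tested and adjusted over the list alone.

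Genes are named by a rule: in each comparison of arms up to 10 rises and 10 falls with the largest log2 change among called genes whose CL libraries both lie above or below both CC libraries, for the average those with the same sign in all 4 numbers, for the tests among groups the 10 smallest p, for each pair of numbers up to 5 rises and 5 falls without overlap of the 4 against 4 libraries, 9 genes always (MYC, MAX, SUPT16H, SSRP1, ADAR, ZBP1, TOP1, TOP2A and TOP2B), and up to 4 members of a list where its result is given. BTG2, the olfactory receptor genes and the interaction genes beyond the first 10 were chosen after their values were seen. The comparisons, tests planned, gene lists and this rule were set before the data were examined. The filter of 50 CPM, the pseudocount and the change of test were set after the unit of the values was known. A gene with 0 reads on one side is given as a lower bound against 3 reads over the group, and one with 1 to 3 reads as a ratio with its exact 95% counting interval.

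The tests were checked on simulated counts with the depths of these libraries, 200 genes changed and a dispersion of 0.005. Of genes changed 2-fold, 24.4% were recovered in zdna1 CL over CC (4608 genes tested), 27.0% in zdna2 (4679), 3.14% in zdna3 (4649) and 9.23% in zdna4 (4626), and of those changed 4-fold 88.1% (4611), 86.8% (4634), 50.5% (4639) and 62.6% (4663). In zdna4 the 4-fold simulation gave 25 false calls, all higher in CL, and the average 13, all higher. Lower were 19 of 20 between zdna4 and zdna1, 18 of 20 between zdna3 and zdna1 and between zdna4 and zdna2, and 12 of 13 between zdna3 and zdna2. Of 2-fold changes 73.4% were recovered for the average (4628), 44.1% for zdna3 against zdna1 (4638). With zdna3 CL alone changed, the test of equal arm differences gave 0.529% of 2-fold and 22.6% of 4-fold (4660 and 4649). Without simulated changes limma called 2 genes in zdna4 and 1 between zdna4 and zdna2. The list test called a simulated raised list, and 3 of 200 unchanged lists had a p under 0.05.

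Alternatives changed the scaling, pseudocount, filter, model, test and libraries used. Where a library was left out, the lone sample of its group was assumed to vary like that group did in the full fit. Genes under the filter were left out of the gene tests because 1 read in a shallow library exceeds most of their level. Genes tied to sex, and a few genes that the naming rule picks, are not reported here. Also used were R 4.3.3, python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.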

Results

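Total RNA was sequenced from U2OS, a human osteosarcoma cell line, in 16 libraries. The labels give each library a number, zdna1 to zdna4, and an arm, CC or CL, with 2 replicates in each of the 8 groups. They spell out neither the numbers nor the arms, so no arm is called a control and each change between arms is given as CL over CC. The series title names MYC, a transcription factor, and FACT, the histone chaperone formed by SUPT16H and SSRP1. It also names Z-DNA, the left-handed form of the double helix. The files of each number hold 1 extra reference sequence of their own, called the contig here. It is counted as 1 gene on the plus strand over its whole length, positions 1 to 198 for zdna1 and zdna4 and 1 to 190 for zdna2 and zdna3.

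Reads assigned to human genes ran from 39335 and 40886 in the replicates of zdna4 CC to 310187 and 225177 in zdna4 CL, with 55606 and 42494 in zdna3 CC and 79181 and 83269 in zdna3 CL. Levels are given in CPM, reads scaled to a common library total, and 1 read stood for 3.22 to 25.4 CPM, so changes in weakly expressed genes were not detectable at this depth. RN7SK, the RNA that holds the elongation kinase P-TEFb inactive, took 2.46% to 4.10% of human-gene reads, and the ribosomal protein genes 3.13% to 4.17%.

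Over the 919 genes of at least 200 CPM, 16 of 16 libraries were closest to a library of their own number, and 13 of 16 to their own replicate. The first principal component held 28.9% of the variance and placed the zdna4 CC libraries at one end and the 4 zdna3 libraries at the other. The zdna4 CC libraries also stood apart by reads in olfactory receptor genes, which are silent in most tissues. These 398 genes summed to 1471 ± 30.3 CPM (mean ± SD, n = 2) in zdna4 CC, against 103 ± 4.70 CPM in zdna4 CL and 55.3 to 396 CPM across the other 14 libraries. Untested weak genes took 25.1 ± 0.893% of the reads in zdna4 CC, and the means of the other groups ran from 15.7% to 17.2%.

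**Figure D1:**
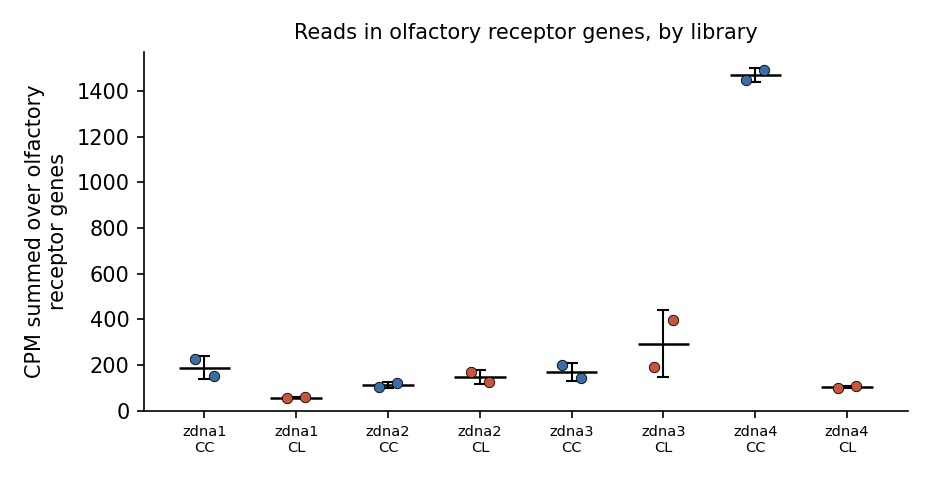
Reads summed over 398 olfactory receptor genes, in CPM, for each of the 16 libraries (points) with the group mean and SD (n = 2).

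The contig's RNA was lower in CL than in CC in zdna1, zdna3 and zdna4, and its level differed widely between numbers. In zdna1 it fell from 361 ± 20.3 reads per 1000 human-gene reads in CC to 3.66 ± 0.554 in CL (mean ± SD, n = 2), a CC over CL ratio of 98.6. In zdna3 it fell from 7028 ± 107 to 269 ± 9.33, a ratio of 26.2. In zdna4 it fell from 188 ± 40.3 to 13.5 ± 0.866, a ratio of 13.9. In zdna2 it stood at 1769 ± 47.8 in CC and 1538 ± 49.9 in CL, a ratio of 1.15. Contig reads were 87.5% of all assigned reads in zdna3 CC and 0.365% in zdna1 CL, with the other groups at 1.34% to 63.9%.

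On the log2 scale the contig's CL over CC difference by limma was -6.59 (SE 0.0519, adjusted p = 5.15e-69) in zdna1, -4.67 (SE 0.0840, adjusted p = 2.40e-48) in zdna3 and -3.88 (SE 0.0838, adjusted p = 7.75e-44) in zdna4. In zdna2 it was -0.19 (SE 0.0526, adjusted p = 0.126, not called). Averaged over the numbers it was -3.83 (SE 0.0349, adjusted p = 2.59e-65), and the 4 differences were not equal (adjusted p = 5.98e-58). On the deposited scale the CC over CL ratios were 85.5, 1.12, 14.3 and 11.4 for zdna1 to zdna4. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so these calls rest on the spread that limma pools across genes. The zdna2 difference passed the test when only the 4 zdna2 libraries were fitted (-0.17).

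**Figure D2:**
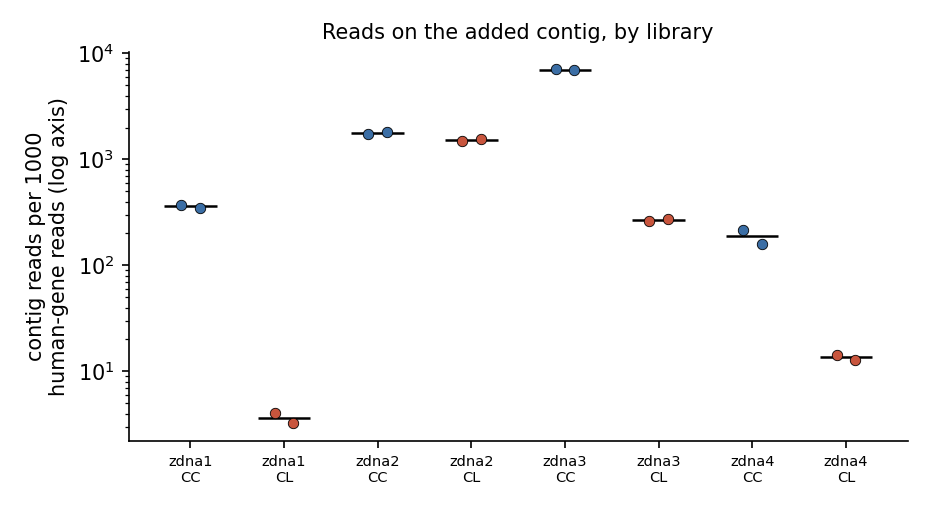
Contig reads per 1000 human-gene reads on a log axis, for each library (points) of zdna1 to zdna4 in CC and CL, with the group mean (line, n = 2). Group means run from 3.66 in zdna1 CL to 7028 in zdna3 CC.

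CL against CC within zdna1 asks which genes differ between the arms when the number is held. RN7SL1, the RNA of the signal recognition particle (hg19 chromosome 14, 50053298 to 50053596, plus strand), rose by 1.13 (SE 0.0659, adjusted p = 5.62e-21) on the log2 scale, from 4617 ± 172 to 10106 ± 406 CPM (mean ± SD, n = 2). IGFBP5, an insulin-like growth factor binding protein, rose by 1.61 (SE 0.254, adjusted p = 2.28e-05) and FTH1, the ferritin heavy chain, by 1.44 (SE 0.314, adjusted p = 0.00723). SYNE1, a giant protein of the nuclear envelope, fell by 1.68 (SE 0.263, adjusted p = 2.28e-05). The nuclear long noncoding RNA MALAT1 (hg19 chromosome 11, 65265209 to 65273983) fell by 1.12 (SE 0.244, adjusted p = 0.00723). GADD45A, a growth arrest and DNA damage gene, fell by 1.00 (SE 0.245, adjusted p = 0.0227), and EP300, a histone acetyltransferase, by 0.87 (SE 0.189, adjusted p = 0.00723).

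Other named genes higher in zdna1 CL, in log2, were RNU6ATAC (2.16), RNA5S9 (1.21), COL5A1 (1.19), MIR663A (1.05), TTYH3 (0.94), EXTL3 (0.89) and GNB1 (0.82). Lower were YTHDC1 (-1.46), FTSJ3 (-1.06), SNAPC1 (-0.87), TARS1 (-0.84) and TRIO (-0.75). TTN, the muscle protein titin, was lower in CL with a CC over CL ratio of 9.10 (95% interval 2.16 to 81.2, 17 against 2 reads), and edgeR did not call it (adjusted p = 0.0611). Its 9, 8, 0 and 2 reads lie near the 6.77, 7.04, 2.17 and 2.44 that the density of olfactory receptor reads predicts.

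Of the 15 nonpolyadenylated and nuclear RNAs, 4 rose and 1 fell over all genes, 8 and 1 adjusted over the list alone. Their median was 0.32 (camera adjusted p = 9.24e-10, adjusted p = 0.0491 with an estimated correlation). Besides RN7SL1 the rises included RMRP, the RNA of RNase MRP (0.70), RPPH1, the RNA of RNase P (0.53), and RN7SL2 (0.45). Of the 22 extracellular matrix and osteoblast genes, 2 rose and 0 fell over all genes, 2 and 0 adjusted over the list alone. Their median was 0.26 (camera adjusted p = 1.21e-04, adjusted p = 0.0185 with an estimated correlation). The members that rose were THBS1, thrombospondin 1 (0.67), and the collagen gene COL5A1. Of the 16 genes of cholesterol and fatty acid synthesis, 0 passed limma's test over all genes, 4 had an unadjusted p under 0.05, and edgeR called 0. Adjusted over the list alone, 2 rose and 0 fell. Their median was 0.48 (camera adjusted p = 5.71e-04, adjusted p = 0.0263 with an estimated correlation). SCD was at 0.66 and FADS2 at 0.78. Of the 32 MYC-activated ribosome biogenesis and nucleolar genes, 0 passed limma's test over all genes, 10 had an unadjusted p under 0.05, and edgeR called 0. Adjusted over the list alone, 0 rose and 1 fell. Their median was -0.34 (camera adjusted p = 2.42e-06, adjusted p = 0.0140 with an estimated correlation). DDX18 was at -0.85, GNL3 at -0.72 and NOLC1 at -0.55.

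In zdna1, 35 of 4632 human genes passed the test, 23 higher and 12 lower. By edgeR 47 passed (33 higher), 34 of them shared. An unadjusted p under 0.05 was found for 489 genes, against 232 by chance. The limma count was 10 without zdna1 CC replicate 1 and 19 without zdna1 CL replicate 1, and DESeq2 called 15. The deposited scale gave 41 (36 higher).

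CL against CC within zdna2 asks the same of the number in which the contig's difference did not pass the test. Genes of the hypoxia and glycolysis list were lower in CL: LDHA, lactate dehydrogenase A, fell by 0.58 (SE 0.113, adjusted p = 0.00297). NDRG1, a hypoxia-induced gene (hg19 chromosome 8, 134249418 to 134309495), fell by 1.03 (SE 0.209, adjusted p = 0.00594), from 518 ± 78.2 to 249 ± 36.4 CPM (mean ± SD, n = 2). The linker histone gene H1-2 fell by 0.54 (SE 0.124, adjusted p = 0.0351), and AHNAK, a large scaffold protein, by 0.37 (SE 0.0878, adjusted p = 0.0493). The collagen gene COL27A1 rose by 1.70 (SE 0.329, adjusted p = 0.00297) and RN7SL1 by 0.50 (SE 0.0668, adjusted p = 2.75e-06). RMRP (hg19 chromosome 9, 35657748 to 35658015) rose by 0.43 (SE 0.0774) and RPPH1 (hg19 chromosome 14, 20811230 to 20811570) by 0.41 (SE 0.0697).

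Of the 23 hypoxia and glycolysis genes, 0 rose and 2 fell over all genes, 0 and 5 adjusted over the list alone. Their median was -0.28 (camera adjusted p = 0.00298, adjusted p = 0.0373 with an estimated correlation). Of the 22 replication-dependent histones, 0 rose and 1 fell over all genes, 0 and 1 adjusted over the list alone. Their median was -0.26 (camera adjusted p = 8.00e-05, adjusted p = 0.0373 with an estimated correlation). Of the 41 mitotic (G2/M) genes, 0 passed limma's test over all genes, 4 had an unadjusted p under 0.05, and edgeR called 0. Adjusted over the list alone, 0 rose and 0 fell. Their median was -0.21 (camera adjusted p = 0.00343, adjusted p = 0.0373 with an estimated correlation). TOP2A was at -0.46. Among the 15 nonpolyadenylated and nuclear RNAs, 3 rose and 0 fell over all genes, 3 and 0 adjusted over the list alone. Their median was 0.07 (camera adjusted p = 1.64e-06, adjusted p = 0.105 with an estimated correlation).

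In zdna2, 8 of 4632 human genes passed the test, 4 higher and 4 lower. By edgeR 9 passed (5 higher), 7 of them shared. An unadjusted p under 0.05 was found for 305 genes, against 232 by chance. For AHNAK edgeR's adjusted p was 0.0963. The count became 1 without zdna2 CC replicate 1, 3 without zdna2 CC replicate 2 and 4 without zdna2 CL replicate 1. It was 2 by DESeq2, 0 without array weights and 5 (4 higher) on the deposited scale.

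CL against CC within zdna3 compares the arms in the number with the highest contig level in CC. The 3 called genes that fell were small structured RNAs. RNU12, the U12 RNA of the minor spliceosome, fell by 1.48 (SE 0.285, adjusted p = 0.00619), and RNU5E-1, a U5 spliceosomal RNA, by 0.84 (SE 0.171, adjusted p = 0.0107). RN7SL1 fell by 0.52 (SE 0.107, adjusted p = 0.0120), from 8831 ± 1318 to 6141 ± 203 CPM (mean ± SD, n = 2), and on the deposited scale its change turned to 0.31. On that scale the median gene was higher in CL by 0.72. LRBA, a protein of vesicle traffic, was higher in CL with a ratio of 10.9 (95% interval 1.72 to 453, 18 against 1 reads), which edgeR did not call (adjusted p = 0.368).

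Of the 15 nonpolyadenylated and nuclear RNAs, 0 rose and 1 fell over all genes, 0 and 2 adjusted over the list alone. Their median was -0.16, 0.64 on the deposited scale (camera adjusted p = 7.15e-04, adjusted p = 0.387 with an estimated correlation). Among the 22 replication-dependent histones, 0 passed limma's test over all genes, 2 had an unadjusted p under 0.05, and edgeR called 0. With p adjusted over the list alone, 0 rose and 0 fell. Their median was 0.30 (camera adjusted p = 0.0440, adjusted p = 0.387 with an estimated correlation). H1-1 was at 1.38 and H4C5 at 0.85. In zdna3, 4 of 4632 human genes passed the test, 1 higher and 3 lower. By edgeR 5 passed (1 higher), 3 of them shared. An unadjusted p under 0.05 was found for 304 genes, against 232 by chance. Called genes numbered 33 without zdna3 CC replicate 1, 1 without zdna3 CL replicate 1 and 1 without zdna3 CL replicate 2. On the deposited scale the count was 1049, all higher in CL.

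CL against CC within zdna4 sets the deepest libraries against the shallowest, and the CC libraries carried 1471 ± 30.3 CPM of olfactory receptor reads against 103 ± 4.70 in CL (mean ± SD, n = 2). Genes of mitosis were higher in CL: TOP2A, the DNA topoisomerase of dividing cells, rose by 1.16 (SE 0.279, adjusted p = 0.0246). KIFC1, a mitotic kinesin, was higher with a ratio of 7.19 (95% interval 1.94 to 60.2, 96 against 2 reads). JUN, an AP-1 transcription factor (hg19 chromosome 1, 59246463 to 59249719), rose by 2.96 (SE 0.452, adjusted p = 1.14e-05). It stood at 0 and 132 CPM in the CC libraries and at 246 and 326 CPM in CL. FOSL1, another AP-1 subunit, fell by 1.85 (SE 0.467, adjusted p = 0.0338). HK2, a hexokinase of glycolysis, fell by 1.64 (SE 0.408, adjusted p = 0.0317) and NDRG1 by 1.35 (SE 0.333, adjusted p = 0.0309). ERRFI1, a feedback inhibitor of the EGF receptor, fell by 2.13 (SE 0.508, adjusted p = 0.0238).

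The largest differences in zdna4 were in genes with many reads in CC and few in the other libraries. LOC150051 (hg19 chromosome 21, 32931546 to 32932800) had 168 and 97 reads in CC and 2 and 0 in CL, a CC over CL ratio of 884 (95% interval 242 to 7339.6, 265 against 2 reads). DOCK6, a guanine nucleotide exchange factor (hg19 chromosome 19, 11309971 to 11373200), had 344 and 196 reads in CC and 11 and 6 in CL, a log2 change of -7.41 (SE 0.726, adjusted p = 3.28e-11). TTN fell by 3.88 (SE 0.807, adjusted p = 0.00472), with 35 reads in CC where the density of olfactory receptor reads predicts 32.0 over its exons. MAP2K3 (-2.12) and VEZF1 (-1.53) were lower.

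Other named genes of zdna4 had 0 reads in both CC libraries and are given against a floor of 3 reads over the group. FLJ22447 was at least 2.65-fold, LAPTM4B at least 2.30-fold and GET3 at least 2.05-fold higher in CL. PAGE2B was at least 1.95-fold, SNORA53 at least 1.90-fold and GLRX3 at least 1.65-fold higher, and edgeR called 1 of these 6, FLJ22447. CPSF6, a factor of mRNA 3' end cleavage, was higher with a ratio of 11.1 (95% interval 1.93 to 444, 74 against 1 reads). DCBLD1 was higher with a ratio of 12.1 (95% interval 2.12 to 485, 81 against 1 reads).

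Among the 41 mitotic (G2/M) genes, 3 rose and 0 fell over all genes, 5 and 0 adjusted over the list alone. Their median was 0.43 (camera adjusted p = 3.56e-04, adjusted p = 0.0235 with an estimated correlation). CKAP2L, a mitotic spindle protein, rose by 2.34 (SE 0.636, adjusted p = 0.0486). Of the 17 heat shock genes, 0 passed limma's test over all genes, 5 had an unadjusted p under 0.05, and edgeR called 3. Adjusted over the list alone, 5 rose and 0 fell. Their median was 0.26 (camera adjusted p = 0.0243, adjusted p = 0.204 with an estimated correlation). HSP90AA1 was at 0.70 and HSPB1 at 1.04. Among the 32 MYC-activated ribosome biogenesis and nucleolar genes, 0 passed limma's test over all genes, 4 had an unadjusted p under 0.05, and edgeR called 0. With p adjusted over the list alone, 0 rose and 0 fell. Their median was -0.25, 0.08 on the deposited scale, 0.17 with TMM over every row (camera adjusted p = 0.0175, adjusted p = 0.119 with an estimated correlation). WDR43 was at -0.81 and NOP58 at 1.52.

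In zdna4, 54 of 4632 human genes passed the test, 42 higher and 12 lower. By edgeR 82 passed (38 higher), 35 of them shared. An unadjusted p under 0.05 was found for 483 genes, against 232 by chance. On simulated 4-fold changes at these depths limma made 25 false calls here, all of them higher in CL. The limma count was 31 without zdna4 CL replicate 2, 17 when only the 4 zdna4 libraries were fitted and 125 without array weights, and DESeq2 called 23. It reached 85 (76 higher) by library totals, 212 (206 higher) on the deposited scale and 439 (431 higher) with TMM over every row, where the median gene of CL over CC stood at 0.17, 0.43 and 0.52 against 0.08.

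**Figure D3:**
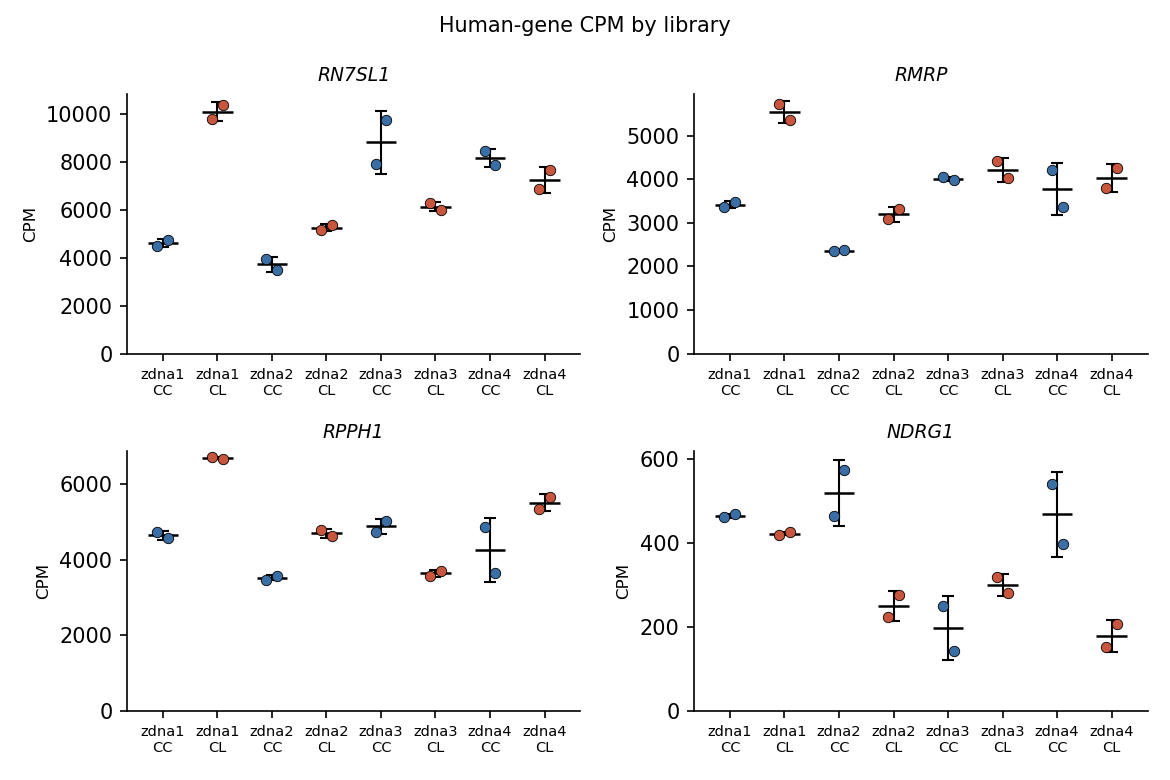
Levels of RN7SL1, RMRP, RPPH1 and NDRG1 in CPM for each library (points) of zdna1 to zdna4 in CC and CL, with the group mean and SD (n = 2). RN7SL1 is higher in CL in zdna1 (log2 1.13) and zdna2 (0.50) and lower in zdna3 (-0.52, 0.31 on the deposited scale), and NDRG1 is lower in CL in zdna2 (-1.03) and zdna4 (-1.35).

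Averaged over the 4 numbers, the comparison asks what the arms have in common. ACTB, beta-actin, was higher in CL by 0.23 (SE 0.0396, adjusted p = 3.04e-04), and FLNA, the actin crosslinker filamin A, by 0.25 (SE 0.0483, adjusted p = 0.00266). ACTG1, gamma-actin, was higher by 0.26 (SE 0.0616) and GAPDH, a glycolytic enzyme, by 0.21 (SE 0.0505, adjusted p = 0.0343). RMRP rose by 0.33 (SE 0.0514, adjusted p = 9.27e-05) and EXTL3, a glycosyltransferase of heparan sulfate synthesis, by 0.69 (SE 0.146, adjusted p = 0.00762). SPARC, a matrix protein of bone, rose by 0.38 (SE 0.0906, adjusted p = 0.0318). The small nucleolar RNA SNORD33 (0.63) was also higher on average, as were KIFC1 (edgeR adjusted p = 0.0826) and PAGE2B, which hold 2 and 0 reads in zdna4 CC.

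Among the 16 genes of cholesterol and fatty acid synthesis, 0 passed limma's test over all genes, 7 had an unadjusted p under 0.05, and edgeR called 1. With p adjusted over the list alone, 5 rose and 0 fell. Their median was 0.34 (camera adjusted p = 1.86e-04, adjusted p = 0.0236 with an estimated correlation). FADS1 was at 0.66. Of the 32 MYC-activated ribosome biogenesis and nucleolar genes, 0 passed limma's test over all genes, 1 had an unadjusted p under 0.05, and edgeR called 0. Adjusted over the list alone, 0 rose and 0 fell. Their median was -0.14, 0.17 on the deposited scale (camera adjusted p = 2.29e-04, adjusted p = 0.0236 with an estimated correlation). Of the 41 mitotic (G2/M) genes, 1 rose and 0 fell over all genes, 2 and 0 adjusted over the list alone. Their median was 0.15 (camera adjusted p = 0.0298, adjusted p = 0.0950 with an estimated correlation). Among the 22 extracellular matrix and osteoblast genes, 1 rose and 0 fell over all genes, 3 and 0 adjusted over the list alone. Their median was 0.16 (camera adjusted p = 0.0298, adjusted p = 0.106 with an estimated correlation). Among the 15 nonpolyadenylated and nuclear RNAs, 4 rose and 0 fell over all genes, 6 and 0 adjusted over the list alone. Their median was 0.09 (camera adjusted p = 7.93e-04, adjusted p = 0.367 with an estimated correlation). Averaged over the numbers, 20 of 4632 human genes passed the test, 16 higher and 4 lower. By edgeR 27 passed (23 higher), 16 of them shared. An unadjusted p under 0.05 was found for 430 genes, against 232 by chance.

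The averaged count was 11 without zdna1 CC replicate 1, 10 without zdna2 CC replicate 2 and 11 without zdna2 CL replicate 2. It was 10 without zdna3 CL replicate 1 and 12 without zdna4 CC replicate 1, and 5 without the 4 zdna4 libraries. It was 8 in a model with 1 arm effect for all numbers and 1019 (1015 higher) on the deposited scale, where the median gene was higher in CL by 0.34.

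The test of whether the CL over CC difference varies between numbers asks which genes respond differently to the arm. RN7SL1's log2 differences were 1.13, 0.50, -0.52 and -0.17 in zdna1 to zdna4 (adjusted p = 2.11e-16), and those of RPPH1 0.53, 0.41, -0.43 and 0.39 (adjusted p = 9.03e-06). NDRG1 ran -0.14, -1.03, 0.63 and -1.35 (adjusted p = 0.00867) and TUBB, a beta-tubulin gene, 0.52, -0.11, -0.16 and 1.09 (adjusted p = 8.58e-06). AHNAK ran 0.31, -0.37, 0.12 and 0.73 (adjusted p = 1.11e-05) and JUN -0.17, 0.12, 0.26 and 2.96 (adjusted p = 8.28e-04). Values that turn on the deposited scale are RN7SL1 (0.31), RPPH1 (0.40) and TUBB (0.66) in zdna3, RN7SL1 in zdna4 (0.21) and NDRG1 in zdna1 (0.03). By limma 40 of 4632 human genes passed and by edgeR 65, 36 of them called by both. The count became 25 without zdna2 CC replicate 1 and 22 without the 4 zdna4 libraries. It was 131 with TMM over every row and 339 on the deposited scale.

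Differences among the numbers, averaged over the arms, asked which genes set the 4 numbers apart, and zdna3 stood out. MYC itself (hg19 chromosome 8, 128747680 to 128755197) averaged 1014 ± 93.3 CPM in zdna3 (mean ± SD, n = 4) against 329.8 ± 73.9 in zdna1, 402 ± 41.2 in zdna2 and 312 ± 109.6 in zdna4. JUN averaged 768 ± 98.3 CPM in zdna3 and 217 ± 26.1 in zdna1. EGR1, a growth-factor-induced zinc finger gene, averaged 357 ± 98.5 and 47.5 ± 8.48 CPM, and CCN2, a matricellular growth factor, 752 ± 101 and 217 ± 73.6. DDIT4, a stress-induced inhibitor of mTORC1, averaged 24.9 ± 17.9 CPM in zdna3 and 232 ± 41.2 in zdna1, and MALAT1 70.4 ± 25.6 and 229.9 ± 102.

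In the test of any difference among numbers 410 of 4632 genes passed and 528 by edgeR, 384 of them called by both. The smallest p-values were those of RN7SL1, RN7SL2, THBS1, RMRP, SNORA73A, CCN2, MALAT1, DOCK6, RNU4-2 and RN7SK. Their adjusted p ran from 1.81e-18 for RN7SL1 to 8.94e-10 for RN7SK. The count was 272 by DESeq2, 736 with TMM over every row and 4386 on the deposited scale.

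**Figure D4:**
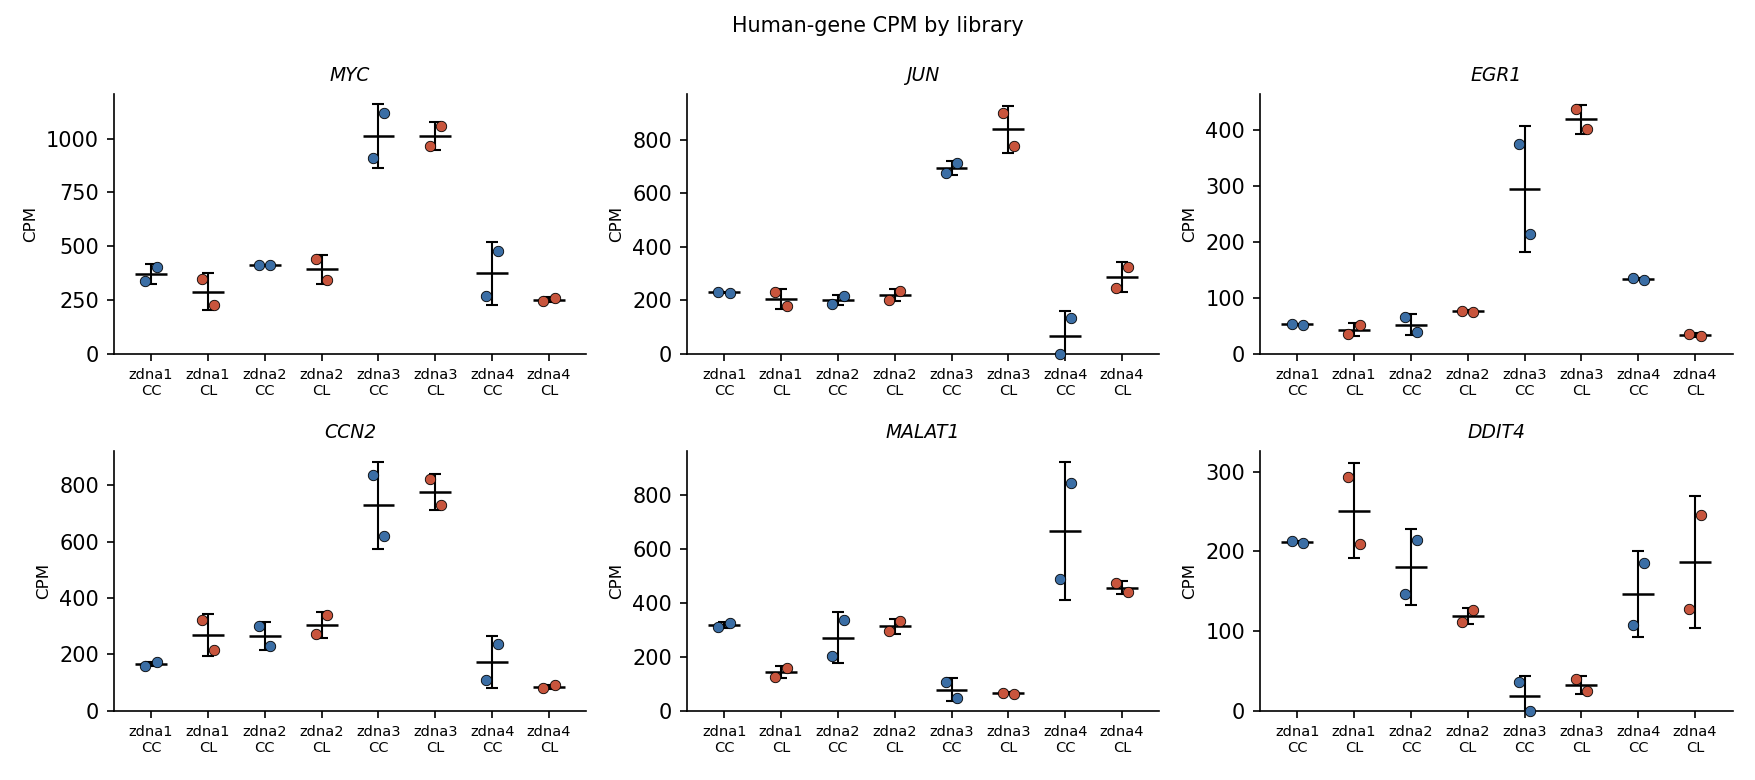
Levels of MYC, JUN, EGR1, CCN2, MALAT1 and DDIT4 in CPM for each library (points), with the mean and SD of each number and arm. Over 4 libraries MYC averages 1014 CPM and DDIT4 24.9 CPM in zdna3, against 329.8 and 232 in zdna1. On the deposited scale MYC's difference from zdna1 is -0.013 in log2.

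Set against zdna1, zdna3 had higher FOS, by 2.97 (SE 0.468, adjusted p = 8.45e-06) in log2, and FOSB, by 2.94 (SE 0.486, adjusted p = 2.27e-05), both subunits of AP-1. GEM, a GTPase induced by growth factors, rose by 2.76 (SE 0.517, adjusted p = 1.93e-04) and EGR1 by 2.64 (SE 0.329, adjusted p = 4.50e-08). NFATC2, a calcium-regulated transcription factor, rose by 2.31 (SE 0.50, adjusted p = 0.00170). DDIT4 fell by 3.01 (SE 0.345, adjusted p = 5.88e-09), and MLLT11 (-1.95), DNAJC14 (-1.95) and SDC3 (-1.93) were lower. POLA1, the catalytic subunit of DNA polymerase alpha, was lower with a zdna1 over zdna3 ratio of 6.99 (95% interval 2.25 to 35.1, 47 against 3 reads). MYC rose by 1.62 (SE 0.174, adjusted p = 1.09e-09), a difference that was -0.013 on the deposited scale. There the median gene stood at -1.48 in zdna3, so directions of gene groups are relative to the other human genes, and medians on that scale stand beside them.

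Of the 21 immediate early genes, 8 rose and 0 fell over all genes, 11 and 1 adjusted over the list alone. Their median was 0.75, -0.74 on the deposited scale (camera adjusted p = 1.70e-13, adjusted p = 3.90e-04 with an estimated correlation). The smallest p-values were those of CCN2 (1.79), EGR1, ATF3 (2.01) and JUN (1.78). Of the 22 replication-dependent histones, 9 rose and 0 fell over all genes, 14 and 0 adjusted over the list alone. Their median was 0.66, -0.87 on the deposited scale (camera adjusted p = 6.62e-16, adjusted p = 3.90e-04 with an estimated correlation). In that list 22 of 22 values were above 0, with H1-2 at 0.86 and H2BC11 at 1.5. Of the 22 TGF-beta and YAP targets, 6 rose and 0 fell over all genes, 7 and 0 adjusted over the list alone. Their median was 0.29, -1.25 on the deposited scale (camera adjusted p = 1.88e-05, adjusted p = 0.00905 with an estimated correlation). ANKRD1 rose by 1.38 and INHBA by 1.51. Among the 23 hypoxia and glycolysis genes, 0 rose and 4 fell over all genes, 0 and 9 adjusted over the list alone. Their median was -0.38 (camera adjusted p = 3.31e-05, adjusted p = 0.00905 with an estimated correlation). Those that fell were SLC2A1, a glucose transporter (-1.37), NDRG1 (-0.87), HK2 (-0.94) and LDHA (-0.38). Of the 22 p53 targets, 0 rose and 4 fell over all genes, 1 and 9 adjusted over the list alone. Their median was -0.67 (camera adjusted p = 4.26e-06, adjusted p = 0.0296 with an estimated correlation). The falls were MDM2, the p53 ubiquitin ligase (-1.11), CDKN1A, a cell cycle inhibitor (-0.88), EDA2R and RRM2B. Of the 16 genes of cholesterol and fatty acid synthesis, 3 rose and 0 fell over all genes, 3 and 0 adjusted over the list alone. Their median was 0.41, -1.07 on the deposited scale (camera adjusted p = 1.70e-04, adjusted p = 0.0120 with an estimated correlation). The rises included HMGCS1 (1.38).

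Of the 8 NF-kB and inflammatory genes, 3 rose and 0 fell over all genes, 3 and 0 adjusted over the list alone. Their median was 0.51, -0.92 on the deposited scale (camera adjusted p = 0.00249, adjusted p = 0.0296 with an estimated correlation). NFKBIA, the NF-kB inhibitor, rose by 2.05. Among the 17 heat shock genes, 2 rose and 0 fell over all genes, 2 and 0 adjusted over the list alone. Their median was 0.27, -1.29 on the deposited scale (camera adjusted p = 7.19e-04, adjusted p = 0.0305 with an estimated correlation). HSPA8 rose by 0.85. Of the 22 extracellular matrix and osteoblast genes, 4 rose and 0 fell over all genes, 5 and 0 adjusted over the list alone. Their median was 0.09, -1.5 on the deposited scale, -0.06 with TMM over every row (camera adjusted p = 0.00196, adjusted p = 0.0241 with an estimated correlation). THBS1 rose by 1.22. Among the 32 MYC-activated ribosome biogenesis and nucleolar genes, 3 rose and 0 fell over all genes, 6 and 0 adjusted over the list alone. Their median was 0.32, -1.21 on the deposited scale (camera adjusted p = 0.00249, adjusted p = 0.0292 with an estimated correlation). NOLC1 rose by 0.92 and NCL by 0.42. Of the 10 genes of the MYC network and FACT, 1 rose and 0 fell over all genes, 2 and 0 adjusted over the list alone. Their median was 0.14, -1.39 on the deposited scale, -0.01 with TMM over every row (camera adjusted p = 0.0158, adjusted p = 0.0556 with an estimated correlation). The member that rose was MYC. Of the 11 MYC-repressed genes, 2 rose and 2 fell over all genes, 2 and 2 adjusted over the list alone. Their median was 0.11, -1.51 on the deposited scale, -0.04 with TMM over every row (camera adjusted p = 0.0413, adjusted p = 0.116 with an estimated correlation). THBS1 and GADD45A rose, and NDRG1 and CDKN1A fell. Of the 28 DNA repair genes, 0 rose and 1 fell over all genes, 0 and 2 adjusted over the list alone. Their median was -0.16 (camera adjusted p = 0.0424, adjusted p = 0.0734 with an estimated correlation). The member that fell was PRKDC, a DNA end-joining kinase (-0.55). Of the 15 nonpolyadenylated and nuclear RNAs, 1 rose and 5 fell over all genes, 3 and 5 adjusted over the list alone. Their median was -0.24 (camera adjusted p = 0.0147, adjusted p = 0.282 with an estimated correlation). RNU4-2 fell by 0.66 and RN7SL2 rose by 0.40.

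Between zdna3 and zdna1, 208 genes passed the test, 103 higher and 105 lower. By edgeR 258 passed (158 higher), 187 of them shared. Called genes numbered 95 without zdna3 CC replicate 2 and 133 without zdna3 CL replicate 1. The number was 118 with CL libraries alone, 117 by DESeq2, 300 (64 higher) with TMM over every row and 4421 (4 higher) on the deposited scale.

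Set against zdna2, zdna3 had higher FOS, an AP-1 subunit, by 3.12 (SE 0.469, adjusted p = 2.50e-06). NFATC2 (2.84) and FLJ16779 (2.45) were higher, and FOSB with a ratio of 48.5 (95% interval 15.9 to 241, 69 against 3 reads). DDIT4 fell by 2.38 (SE 0.346, adjusted p = 1.12e-06) and MALAT1 by 1.93 (SE 0.234, adjusted p = 1.17e-08). DNAJC14 (-1.86) and FBXL13 (-1.84) were lower, and POLA1 with a zdna2 over zdna3 ratio of 7.60 (95% interval 2.45 to 38.1, 48 against 3 reads). MYC rose by 1.31 (SE 0.175, adjusted p = 1.35e-07), or -0.21 on the deposited scale, where the median gene stood at -1.36.

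Among the 21 immediate early genes, 9 rose and 1 fell over all genes, 14 and 1 adjusted over the list alone. Their median was 1.09, -0.27 on the deposited scale (camera adjusted p = 1.30e-13, adjusted p = 4.36e-04 with an estimated correlation). The member that fell was BTG2, an antiproliferative gene and p53 target. Among the 16 genes of cholesterol and fatty acid synthesis, 8 rose and 0 fell over all genes, 9 and 0 adjusted over the list alone. Their median was 0.73, -0.61 on the deposited scale (camera adjusted p = 1.24e-09, adjusted p = 0.00112 with an estimated correlation). Among the 22 extracellular matrix and osteoblast genes, 8 rose and 0 fell over all genes, 9 and 0 adjusted over the list alone. Their median was 0.38, -1.05 on the deposited scale (camera adjusted p = 9.87e-08, adjusted p = 0.00167 with an estimated correlation). Among the 22 p53 targets, 0 rose and 8 fell over all genes, 0 and 9 adjusted over the list alone. Their median was -0.70 (camera adjusted p = 9.96e-07, adjusted p = 0.0320 with an estimated correlation). MDM2 fell by 1.25. Among the 22 replication-dependent histones, 9 rose and 0 fell over all genes, 14 and 0 adjusted over the list alone. Their median was 0.61, -0.84 on the deposited scale (camera adjusted p = 4.89e-14, adjusted p = 4.36e-04 with an estimated correlation). Among the 8 NF-kB and inflammatory genes, 3 rose and 0 fell over all genes, 3 and 0 adjusted over the list alone. Their median was 0.70, -0.62 on the deposited scale (camera adjusted p = 0.00119, adjusted p = 0.0272 with an estimated correlation). Among the 22 TGF-beta and YAP targets, 6 rose and 0 fell over all genes, 9 and 1 adjusted over the list alone. Their median was 0.41, -1.02 on the deposited scale (camera adjusted p = 3.90e-05, adjusted p = 0.00993 with an estimated correlation). Of the 17 heat shock genes, 2 rose and 0 fell over all genes, 4 and 0 adjusted over the list alone. Their median was 0.15, -1.21 on the deposited scale, -0.03 with TMM over every row (camera adjusted p = 0.00283, adjusted p = 0.0600 with an estimated correlation). Among the 11 MYC-repressed genes, 2 rose and 0 fell over all genes, 3 and 1 adjusted over the list alone. Their median was 0.29, -1.17 on the deposited scale (camera adjusted p = 0.00459, adjusted p = 0.0564 with an estimated correlation). Among the 15 nonpolyadenylated and nuclear RNAs, 6 rose and 1 fell over all genes, 6 and 2 adjusted over the list alone. Their median was 0.05, -0.03 by library totals, -1.47 on the deposited scale, -0.14 with TMM over every row (camera adjusted p = 8.70e-05, adjusted p = 0.132 with an estimated correlation). Examples of these lists are NFKBIA (1.95), INHBA (1.69), HSPA8 (0.91), THBS1 (1.32) and RN7SL2 (0.84).

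Between zdna3 and zdna2, 278 genes passed the test, 130 higher and 148 lower. By edgeR 316 passed (186 higher), 244 of them shared. The limma count was 147 without zdna3 CC replicate 2 and 130 with CL libraries alone. It was 136 by DESeq2, 305 (103 higher) by library totals, 453 (81 higher) with TMM over every row and 4269 (8 higher) on the deposited scale.

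Set against zdna3, zdna4 had higher MALAT1, by 2.82 (SE 0.280, adjusted p = 3.82e-11), and DDIT4, by 2.51 (SE 0.415, adjusted p = 3.00e-05). SDC3 (2.27), GPSM2 (2.20) and UNC13B (2.20) were higher. JUN fell by 2.88 (SE 0.320, adjusted p = 1.21e-09) and CCN2 by 2.57 (SE 0.256, adjusted p = 3.82e-11), and NFATC2 (-3.52), FOS (-3.32) and FOSB (-2.54) were lower. MYC fell by 1.72 (SE 0.209, adjusted p = 1.43e-08). The zdna4 CC libraries in comparisons of numbers are those with 1471 ± 30.3 CPM of olfactory receptor reads (mean ± SD, n = 2).

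Of the 21 immediate early genes, 0 rose and 8 fell over all genes, 0 and 11 adjusted over the list alone. Their median was -0.95, 0.50 on the deposited scale (camera adjusted p = 7.67e-13, adjusted p = 8.62e-04 with an estimated correlation). Of the 22 TGF-beta and YAP targets, 0 rose and 8 fell over all genes, 0 and 9 adjusted over the list alone. Their median was -0.32, 1.16 on the deposited scale (camera adjusted p = 8.59e-06, adjusted p = 0.0124 with an estimated correlation). Of the 70 ribosomal protein genes, 0 rose and 10 fell over all genes, 0 and 12 adjusted over the list alone. Their median was -0.22, 1.36 on the deposited scale (camera adjusted p = 9.92e-05, adjusted p = 0.0249 with an estimated correlation). Among the 41 mitotic (G2/M) genes, 2 rose and 0 fell over all genes, 3 and 0 adjusted over the list alone. Their median was 0.41 (camera adjusted p = 3.48e-04, adjusted p = 0.0125 with an estimated correlation). The kinetochore motor CENPE rose by 1.5 and the spindle protein ASPM by 1.24. Of the 32 MYC-activated ribosome biogenesis and nucleolar genes, 0 rose and 6 fell over all genes, 0 and 7 adjusted over the list alone. Their median was -0.47, 1.04 on the deposited scale (camera adjusted p = 2.47e-04, adjusted p = 0.0130 with an estimated correlation). Of the 22 extracellular matrix and osteoblast genes, 0 rose and 5 fell over all genes, 1 and 7 adjusted over the list alone. Their median was -0.18, 1.31 on the deposited scale (camera adjusted p = 2.32e-04, adjusted p = 0.0125 with an estimated correlation). Of the 8 NF-kB and inflammatory genes, 0 rose and 2 fell over all genes, 0 and 4 adjusted over the list alone. Their median was -0.93, 0.49 on the deposited scale (camera adjusted p = 0.0050, adjusted p = 0.0393 with an estimated correlation). Of the 22 replication-dependent histones, 0 rose and 4 fell over all genes, 0 and 4 adjusted over the list alone. Their median was -0.26, 1.29 on the deposited scale (camera adjusted p = 0.00458, adjusted p = 0.0389 with an estimated correlation). Among the 17 heat shock genes, 0 rose and 2 fell over all genes, 0 and 2 adjusted over the list alone. Their median was -0.36, 1.18 on the deposited scale (camera adjusted p = 0.00322, adjusted p = 0.0519 with an estimated correlation). Of the 16 genes of cholesterol and fatty acid synthesis, 0 rose and 2 fell over all genes, 0 and 3 adjusted over the list alone. Their median was -0.30, 1.24 on the deposited scale (camera adjusted p = 0.0372, adjusted p = 0.0745 with an estimated correlation). Of the 11 MYC-repressed genes, 0 rose and 2 fell over all genes, 0 and 3 adjusted over the list alone. Their median was -0.32, 1.28 on the deposited scale (camera adjusted p = 0.0177, adjusted p = 0.0745 with an estimated correlation). Among the 28 DNA repair genes, 2 rose and 1 fell over all genes, 2 and 1 adjusted over the list alone. Their median was 0.28 (camera adjusted p = 0.0233, adjusted p = 0.0519 with an estimated correlation). PRKDC (0.52) and ATM (1.23) rose.

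Between zdna4 and zdna3, 220 genes passed the test, 85 higher and 135 lower. By edgeR 288 passed (105 higher), 206 of them shared. The count became 123 without zdna3 CC replicate 2 and 135 without zdna3 CL replicate 1. It was 107 without zdna4 CC replicate 1 and 124 without zdna4 CC replicate 2, and 478 without array weights. The deposited scale gave 3832 (3826 higher), and the median gene was higher in zdna4 by 1.38.

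Between zdna2 and zdna1, nonpolyadenylated RNAs were lower and ribosome biogenesis genes higher in zdna2. RNA5S9, a 5S ribosomal RNA gene, fell by 1.57 (SE 0.193, adjusted p = 2.30e-08) and RN7SL1 by 0.62 (SE 0.0469, adjusted p = 1.32e-15). SYNE1 rose by 1.34 (SE 0.187, adjusted p = 7.47e-07), and DAG1, the matrix receptor dystroglycan, fell by 1.21 (SE 0.194, adjusted p = 1.73e-05). UTP25, a nucleolar protein (0.84), the nuclear receptor gene NR1D2 (0.82), FNIP1 (0.80) and U2SURP (0.77) were higher. MAP1A (-1.33), PLCE1 (-1.27) and FADS3 (-1.21) were lower. Of the 15 nonpolyadenylated and nuclear RNAs, 0 rose and 9 fell over all genes, 1 and 10 adjusted over the list alone. Their median was -0.42 (camera adjusted p = 8.23e-24, adjusted p = 0.0102 with an estimated correlation). RMRP fell by 0.66 and RN7SL2 by 0.44. Among the 32 MYC-activated ribosome biogenesis and nucleolar genes, 7 rose and 0 fell over all genes, 8 and 0 adjusted over the list alone. Their median was 0.20 (camera adjusted p = 3.06e-05, adjusted p = 0.0102 with an estimated correlation). The rises included the nucleolar proteins NCL (0.37) and NPM1 (0.33).

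Of the 23 hypoxia and glycolysis genes, 0 rose and 3 fell over all genes, 0 and 6 adjusted over the list alone. Their median was -0.27 (camera adjusted p = 7.08e-05, adjusted p = 0.0102 with an estimated correlation). TPI1, a glycolytic enzyme, fell by 0.68. Among the 16 genes of cholesterol and fatty acid synthesis, 0 rose and 2 fell over all genes, 0 and 2 adjusted over the list alone. Their median was -0.33 (camera adjusted p = 2.98e-04, adjusted p = 0.0158 with an estimated correlation). FADS2 fell by 1.02. Among the 22 extracellular matrix and osteoblast genes, 0 rose and 2 fell over all genes, 0 and 7 adjusted over the list alone. Their median was -0.25 (camera adjusted p = 8.73e-04, adjusted p = 0.0173 with an estimated correlation). COL1A1 fell by 0.44. Of the 28 S phase and replication genes, 0 rose and 2 fell over all genes, 0 and 2 adjusted over the list alone. Their median was -0.24 (camera adjusted p = 0.00147, adjusted p = 0.0465 with an estimated correlation). The falls were CDT1, a replication licensing factor (-1.45), and LIG1, a DNA ligase (-0.94). Of the 29 transcription elongation and pausing factors, 1 rose and 0 fell over all genes, 1 and 0 adjusted over the list alone. Their median was 0.17 (camera adjusted p = 0.0246, adjusted p = 0.152 with an estimated correlation). AFF4, a scaffold of the super elongation complex, rose by 0.45.

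Between zdna2 and zdna1, 116 genes passed the test, 37 higher and 79 lower. By edgeR 126 passed (48 higher), 105 of them shared. Leaving out any 1 of their 8 libraries lowered the count by over 1.5 times. It was 59 without zdna1 CC replicate 1, 77 without zdna1 CC replicate 2, 67 without zdna1 CL replicate 1 and 74 without zdna1 CL replicate 2. It was 69 without zdna2 CC replicate 1, 68 without zdna2 CC replicate 2, 76 without zdna2 CL replicate 1 and 72 without zdna2 CL replicate 2. It was 128 (5 higher) on the deposited scale and 115 (52 higher) by library totals. DESeq2 called 39, and without array weights limma called 17.

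Between zdna4 and zdna1, histone genes were higher in zdna4. Of the nuclear RNAs, MALAT1 rose by 1.31 (SE 0.232, adjusted p = 3.74e-04) and NEAT1, the paraspeckle RNA, by 0.88 (SE 0.161, adjusted p = 6.63e-04). The histone genes H2AC6, H2BC12 and H2BC21 rose by 1.19, 0.73 and 0.68. SRP68 fell by 1.05 (SE 0.271, adjusted p = 0.0463) and the receptor kinase EPHA2 by 1.05 (SE 0.205, adjusted p = 0.00175). SPRED2 (-1.73), INKA2 (-1.70, edgeR adjusted p = 0.0627) and CDC42SE1 (-1.46) were lower, each with 0 reads in a zdna4 CC library.

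Of the 41 mitotic (G2/M) genes, 2 rose and 0 fell over all genes, 6 and 0 adjusted over the list alone. Their median was 0.35 (camera adjusted p = 1.50e-10, adjusted p = 0.00102 with an estimated correlation). Those that rose were the proliferation marker MKI67 (0.57) and the kinetochore protein CENPF (0.60). Among the 22 replication-dependent histones, 3 rose and 0 fell over all genes, 4 and 0 adjusted over the list alone. Their median was 0.32 (camera adjusted p = 9.32e-09, adjusted p = 0.00265 with an estimated correlation). Among the 70 ribosomal protein genes, 0 rose and 2 fell over all genes, 0 and 5 adjusted over the list alone. Their median was -0.19 (camera adjusted p = 3.52e-07, adjusted p = 0.0138 with an estimated correlation). Of the 22 p53 targets, 0 rose and 2 fell over all genes, 0 and 2 adjusted over the list alone. Their median was -0.35 (camera adjusted p = 5.78e-05, adjusted p = 0.0802 with an estimated correlation). Those that fell were TP53INP1 (-1.85) and BAX (-1.37), a promoter of apoptosis. Among the 23 hypoxia and glycolysis genes, 0 passed limma's test over all genes, 7 had an unadjusted p under 0.05, and edgeR called 1. With p adjusted over the list alone, 0 rose and 3 fell. Their median was -0.28 (camera adjusted p = 3.90e-04, adjusted p = 0.0157 with an estimated correlation). Of the 37 MYC-activated metabolism and proliferation genes, 0 passed limma's test over all genes, 4 had an unadjusted p under 0.05, and edgeR called 0. Adjusted over the list alone, 0 rose and 3 fell. Their median was -0.16 (camera adjusted p = 0.0106, adjusted p = 0.0443 with an estimated correlation). Among the 15 nonpolyadenylated and nuclear RNAs, 2 rose and 4 fell over all genes, 3 and 7 adjusted over the list alone. Their median was -0.21 (camera adjusted p = 0.00238, adjusted p = 0.191 with an estimated correlation). RN7SK fell by 0.26, whereas MALAT1 rose.

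Between zdna4 and zdna1, 32 genes passed the test, 11 higher and 21 lower. By edgeR 34 passed (18 higher), 23 of them shared. Called genes numbered 21 without zdna1 CC replicate 1, 17 without zdna1 CC replicate 2 and 17 without zdna1 CL replicate 1. The number was 88 with CL libraries alone and 147 (9 higher) with TMM over every row, and DESeq2 called 18.

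Between zdna4 and zdna2, genes of mitosis were higher and nucleolar genes lower in zdna4. CCNB2, a mitotic cyclin, rose by 1.57 (SE 0.387, adjusted p = 0.0146) and TUBB3, a beta-tubulin gene, by 1.63 (SE 0.387, adjusted p = 0.0109). LAMA5, a laminin chain, rose by 1.34 (SE 0.303, adjusted p = 0.00743), and LOC107985911 (1.45) and SHOC1 (1.36) were higher. MAP1LC3B, an autophagosome protein, fell by 1.64 (SE 0.380, adjusted p = 0.00807) and the proteasome subunit PSMB2 by 1.44 (SE 0.314, adjusted p = 0.00533). GLRX3 (-2.17), FBXO28 (-1.63) and NXF1 (-1.56) were lower. Among the 41 mitotic (G2/M) genes, 3 rose and 0 fell over all genes, 10 and 0 adjusted over the list alone. Their median was 0.48 (camera adjusted p = 4.11e-12, adjusted p = 6.13e-04 with an estimated correlation). MKI67 rose by 0.76. Of the 32 MYC-activated ribosome biogenesis and nucleolar genes, 0 rose and 5 fell over all genes, 0 and 7 adjusted over the list alone. Their median was -0.42 (camera adjusted p = 5.55e-07, adjusted p = 0.00468 with an estimated correlation). The falls included DDX21 (-0.82), NCL (-0.48) and NPM1 (-0.44).

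Of the 70 ribosomal protein genes, 0 rose and 3 fell over all genes, 1 and 6 adjusted over the list alone. Their median was -0.18 (camera adjusted p = 1.87e-04, adjusted p = 0.0452 with an estimated correlation). Among the 22 p53 targets, 0 rose and 2 fell over all genes, 0 and 5 adjusted over the list alone. Their median was -0.49 (camera adjusted p = 3.56e-05, adjusted p = 0.0684 with an estimated correlation). Of the 22 replication-dependent histones, 3 rose and 0 fell over all genes, 6 and 0 adjusted over the list alone. Their median was 0.35 (camera adjusted p = 6.45e-07, adjusted p = 0.00468 with an estimated correlation). Of the 16 genes of cholesterol and fatty acid synthesis, 1 rose and 0 fell over all genes, 2 and 0 adjusted over the list alone. Their median was 0.45 (camera adjusted p = 2.60e-05, adjusted p = 0.00798 with an estimated correlation). Of the 15 nonpolyadenylated and nuclear RNAs, 5 rose and 1 fell over all genes, 6 and 1 adjusted over the list alone. Their median was 0.16, -0.06 with TMM over every row (camera adjusted p = 4.47e-07, adjusted p = 0.0684 with an estimated correlation). Examples of these lists are RPS4X (-0.50), RRM2B (-0.91), H2BC21 (0.86), ACACA (1.02) and NEAT1 (1.30). Between zdna4 and zdna2, 115 genes passed the test, 57 higher and 58 lower. By edgeR 170 passed (95 higher), 107 of them shared. The limma count was 70 without zdna2 CC replicate 1, 69 without zdna2 CC replicate 2, 34 without zdna4 CC replicate 1 and 70 without zdna4 CC replicate 2. It was 449 with CL libraries alone, 189 (40 higher) by library totals and 383 (36 higher) with TMM over every row, and DESeq2 called 73.

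The genes that the title names, and those that bind Z-DNA or relieve supercoiling, were followed in every comparison. MYC's CL over CC differences were -0.38, -0.09, 0.00 and -0.50 in zdna1 to zdna4 and -0.24 on average. None passed the test (adjusted p = 0.452, 0.983, 0.999, 0.596 and 0.555). Among the numbers MYC differed (adjusted p = 8.94e-10), and zdna2 and zdna4 differed from zdna1 by 0.30 and -0.10 without passing. Of the FACT subunits, SSRP1 changed by -0.64 (SE 0.196, adjusted p = 0.0430) in zdna4 over zdna3, or by 0.93 on the deposited scale, and passed in no other comparison by limma. SUPT16H, MAX, the partner of MYC, ADAR, the RNA-editing enzyme with a Z-DNA-binding domain, TOP1 and TOP2B passed in no comparison by limma. TOP2A passed in zdna4 CL over CC and in the test that the CL over CC differences are equal (adjusted p = 0.00867). ZBP1, a Z-DNA sensor, had 1 read in total and was not tested.

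For the list of Z-DNA binding and double-stranded RNA sensing genes (6 of 16 tested), camera's smallest adjusted p over the 11 comparisons was 0.308. For topoisomerases and supercoiling (9 of 17 tested) it was 0.190.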

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

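The tests of depth in the silent genes, both tests of LOC150051 and DOCK6 and the test of contig RNA level in zdna3 were chosen only after the result was seen; the other tests in this part were set beforehand. The first pattern is a signal outside the tested genes: the olfactory receptor genes summed to 1471 CPM in zdna4 CC. Few human-gene reads alone are argued against: zdna3 CC replicate 2 (42494) had 0.0960 times that level. Its 295431 contig reads leave a low total yield untested. Reads spread evenly over exons, as from genomic DNA, stay open. The receptor genes had 1.49 times the read density of other silent families, but 0.447 to 2.08 times in the other 14 libraries, which does not decide. Transcription of silent genes in that group stays open and was not tested.

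The second pattern is LOC150051 and DOCK6 in zdna4 CC. The even background is argued against, since the gene nearest to it, DOCK6, had 302 times the reads that background predicts for its exons. Reads of the contig assigned to these genes are argued against too: their number per contig read was 0.0479 times as high in zdna4 CL as in CC, where a fixed share of contig reads would give 1. The highest counts in the other 14 libraries were 2 and 11 reads. Reads from another source that covers these places, and a change in their transcription in that group, stay open and were not tested.

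The third pattern is the higher level of immediate early genes in zdna3, a hypothesis found in these data. Thinning every library to 39335 reads left the median of the 21 genes, zdna3 against the other numbers, at 1.02 against 0.75 at full depth, a ratio of 1.35, so lower depth does not account for it, although called genes dropped from 271 to 104. Contig RNA level alone is argued against: zdna3 CL held 269 contig reads per 1000 human-gene reads and zdna2 CL 1538, yet the median was higher in zdna3 CL by 0.89 (17 of 21 genes above 0, resampling genes 0.67 to 1.27). On the deposited scale, which moves all genes of a library alike, the median against zdna1 was -0.74 and that of all genes -1.48. A response of the cells to what sets zdna3 apart, or to how they were handled, may underlie the pattern and was not tested, since each number is a single set of libraries.

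The CL over CC difference varied between numbers for 40 human genes by limma's test, and for the contig, whose log2 differences spanned 6.40. Of the 100 regroupings drawn, 3 gave as many genes, the real one included, with a highest other of 54. Chance differences between cultures stay open, as replicates may share one. The spans between the highest and lowest log2 difference were, for structured RNAs, RN7SL1 (1.64), RN7SL2 (0.63), RN7SK (0.54), RMRP (0.63), RPPH1 (0.95), RNU12 (1.51), RNU5E-1 (1.96) and RNA5S9 (2.03). For other genes of the test they were JUN (3.13), TOP2A (1.62), TUBB (1.25), FOSL1 (2.72) and COL27A1 (3.24). They were also AHNAK (1.10), DAG1 (2.60), FLNC (0.98), GADD45A (1.72), IGFBP5 (2.22), LDHA (0.70), NDRG1 (1.98), SYNE1 (2.09), THBS1 (0.89) and TRIO (0.90). In CPSF6 (3.65), GLRX3 (3.43), LRBA (3.89), TTN (4.23), DOCK6 (8.24) and LOC150051 (8.67) a group holds 3 reads or fewer, so these spans depend on the pseudocount. JUN's span does too, since its zdna4 CC libraries stood at 0 and 132 CPM.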

How the results depend on the processing

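Among the alternatives, edgeR on recovered reads, the deposited scale, TMM over every row, pseudocounts of 5 and 20, filters of 20 and 100 CPM, no array weights, CL libraries alone and fits without the zdna4 libraries were chosen after seeing the data. Scaling by dm6 reads, planned, was not run because no such rows are used here. Of 149 named calls, 146 were kept with RLE factors, 136 by edgeR, 119 on the deposited scale with 4 reversed, 76 by DESeq2 and 61 with a filter of 1 CPM. The calls on weakly expressed genes and the shallow zdna3 and zdna4 CC libraries are where depth limits most. Counts of called genes below are those that moved by over 1.5 times; where more or fewer genes or libraries enter, that is part of the change, and elsewhere the cause was not tested.

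With a replicate block, as if replicates were paired, no count moved by over 1.5 times: zdna1 34, zdna2 7, zdna3 3, zdna4 47, average 18, interaction 40, any number 391, zdna2 against zdna1 115, zdna3 against zdna1 205, zdna4 against zdna1 27, zdna3 against zdna2 278, zdna4 against zdna2 112 and zdna4 against zdna3 211, with 75 list calls.

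Changes of scale gave these counts. Library totals: zdna4 85, zdna4 against zdna2 189. TMM over every row: zdna4 439, average 159, interaction 131, any number 736, zdna4 against zdna1 147, zdna3 against zdna2 453, zdna4 against zdna2 383. The deposited scale: zdna2 5, zdna3 1049, zdna4 212, average 1019, interaction 339, any number 4386, zdna3 against zdna1 4421, zdna3 against zdna2 4269, zdna4 against zdna3 3832. With the TMM factors of the tests the median of all genes lay between -0.05 and 0.08 in every comparison. On the deposited scale it stood at -1.48 in zdna3 against zdna1, -1.36 against zdna2, 1.38 in zdna4 against zdna3, 0.72 in zdna3 CL over CC, 0.43 in zdna4, 0.34 on average and 0.15 in zdna1. With TMM over every row it stood at 0.52 in zdna4, 0.19 on average and between -0.24 and -0.19 in zdna3 and zdna4 against zdna1 and zdna2.

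Changes of test gave these. DESeq2: zdna1 15, zdna2 2, zdna4 23, any number 272, zdna2 against zdna1 39, zdna3 against zdna1 117, zdna4 against zdna1 18, zdna3 against zdna2 136, zdna4 against zdna2 73. EdgeR: zdna4 82, interaction 65. No array weights: zdna1 10, zdna2 0, zdna3 8, zdna4 125, zdna2 against zdna1 17, zdna4 against zdna1 19, zdna4 against zdna3 478. An additive model: average 8. Only the libraries compared: zdna3 7, zdna4 17, and the zdna2 contig, now called, at -0.17. A log2 change of at least 1: zdna1 12, zdna2 2, zdna3 2, average 4, zdna2 against zdna1 17, zdna3 against zdna1 110, zdna4 against zdna1 17, zdna3 against zdna2 145, zdna4 against zdna2 42. Changes of filter gave these. None: zdna3 0, zdna4 122, interaction 12, any number 135, zdna2 against zdna1 27, zdna3 against zdna1 128, zdna4 against zdna1 12, zdna4 against zdna2 9, zdna4 against zdna3 34. At least 1 CPM: zdna1 17, zdna3 0, zdna4 6, interaction 6, any number 92, zdna2 against zdna1 40, zdna3 against zdna1 101, zdna4 against zdna1 1, zdna3 against zdna2 161, zdna4 against zdna2 2, zdna4 against zdna3 17. At least 20 CPM: zdna4 100, average 37. Without the zdna4 libraries: average 5, interaction 22. CL libraries alone: zdna3 against zdna1 118, zdna4 against zdna1 88, zdna3 against zdna2 130, zdna4 against zdna2 449. Where limma counted 0 in zdna3 without a filter or at 1 CPM, 304 genes had an unadjusted p under 0.05 at the filter of 50 CPM, and edgeR called 5. The 0 in zdna2 without array weights stands against 9 by edgeR with 305 genes at an unadjusted p under 0.05.

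On the deposited scale these log2 values, called before or after, reversed. In CL over CC: RN7SL1 0.31, RPPH1 0.40, TUBB 0.66 and SSRP1 0.67 in zdna3, and SSRP1 0.32 on average. In zdna3 against zdna1: MYC -0.013, SUPT16H -1.40, SSRP1 -1.30, ADAR -1.34 and TOP2B -1.24. In zdna3 against zdna2: MYC -0.21, SSRP1 -1.12, ADAR -1.04 and TOP2B -1.26. In zdna4 against zdna3: SUPT16H 1.27, SSRP1 0.93, ADAR 1.15 and TOP1 1.40. The median gene changes in the same direction there.

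Leaving out each library in turn gave zdna1 10 to 45, zdna2 1 to 10, zdna3 1 to 33, zdna4 31 to 61, average 10 to 22, interaction 25 to 50, any number 306 to 395, zdna2 against zdna1 59 to 119, zdna3 against zdna1 95 to 211, zdna4 against zdna1 17 to 40, zdna3 against zdna2 147 to 281, zdna4 against zdna2 34 to 118, zdna4 against zdna3 107 to 219 called genes, and 107 to 138 of the named calls were kept. The libraries that moved a count by over 1.5 times are named beside it in the results. The contig's log2 difference ran -0.23 to -0.16 in zdna2 and -4.71 to -4.66 in zdna3 (zdna1 and zdna4 above).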

Other observations

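None of the tests in this part was chosen after its result was seen. Besides Z-DNA sensing and topoisomerases, camera called 0 of 11 comparisons for 6 lists, of which only the members above the filter were tested. The smallest adjusted p was 0.313 for interferon-stimulated genes (9 of 53 tested), which respond to sensed double-stranded nucleic acid, and 0.121 for oxidative phosphorylation (34 of 46 tested). It was 0.0800 for apoptosis (8 of 29 tested), 0.10 for chromatin assembly and remodelling (31 of 38 tested), 0.0946 for housekeeping genes (18 of 25 tested) and 0.676 for the unfolded protein and integrated stress response (19 of 35 tested). Single members did change: DDIT4, of the last list, was lower in zdna3 than in zdna1 by -3.01 (SE 0.345, adjusted p = 5.88e-09) in log2 (n = 4 per number, tested by limma), and ATF3 higher by 2.01 (SE 0.291, adjusted p = 1.75e-06). Of the mitochondrially encoded genes 0 of 15 are in the files.

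Markers of other cell types stayed low. Over all libraries the 20 epithelial markers summed to a mean of 539 CPM, 18 neural and kidney-line markers to 262, 12 endothelial markers to 77.4 and 22 haematopoietic markers to 66.4, and 2, 2, 0 and 0 of them reached the filter. The CL over CC differences of the 4632 genes hardly correlated between numbers: across genes, which are not independent replicates, Pearson's r over the 6 pairs of numbers ran from -0.0385 to 0.111.

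Regroupings of the libraries were counted with the model of each comparison. For the CL over CC average, 2 of 100 drawn gave at least the real 20 genes, the real one included. The highest other was 22. For any difference among numbers it was 1 of 100, with 410 against 33. Chance between cultures stays open. For the pairs of numbers, each of 35 splits of 8 libraries was run in a model without arm, and the real one alone reached its count each time. The real count and the highest other were 79 and 10 for zdna2 against zdna1, 189 and 4 for zdna3 against zdna1, 81 and 41 for zdna4 against zdna1, 270 and 2 for zdna3 against zdna2, 509 and 235 for zdna4 against zdna2 and 426 and 169 for zdna4 against zdna3. The 41 came from the split by arm, and the 235 and 169 from splits that part the zdna4 CC libraries. The splits by arm of these 2 pairs gave 2 and 0.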
